A study of Mus musculus with 8 samples.

How the data were processed

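RNA was sequenced from GFP-positive fibroblasts flow-sorted from mouse ventricles 4 weeks after transverse aortic constriction. Per the labels, mice carried a tamoxifen-dependent Cre (MerCreMer) in the Postn or the Tcf21 locus and a Cre-dependent GFP reporter, and received tamoxifen at 100 mg/kg for 2 days and then chow dosed at 40 mg/kg. Total RNA was amplified with the NuGEN Ovation RNA-Seq kit, made into libraries with Nextera XT tagmentation and sequenced on an Illumina HiSeq2500, per the labels' protocols. No strand-marking step is described there, so counts of overlapping and antisense genes cannot be told apart by strand. CD31-positive cells served only to normalise cell numbers between digestions. The groups were taken from the sample titles. The HK numbers in them name libraries and pair nothing between groups.

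The authors deposited expected counts per Ensembl gene for each library, named raw in the file headers, with 38087 genes in each of 2 tables. Most were fractional: 12.5% of the values above 0 were whole numbers. Reads were aligned to mm10, per the submitters' processing notes. The aligner, the counting tool and the handling of reads that match several genes are not given in the sources used here. The authors also deposited a log2 value per library, scaled to the library total, floored and centred on each gene's median. Their deposited log2 fold change is the difference between the group means of these log2 values. Their tables also give it as a fold ratio and as a signed fold score, per the file headers. Every gene is listed in them as up or down without a test.

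The expected counts were rounded to whole numbers, and entries with the same gene symbol were summed (278 symbols from 3966 entries, 0.80% to 1.01% of each library's counts), which left 34399 symbols. Of these, 10403 had no count in any library. Levels are given as CPM, the count divided by the library total and multiplied by 1000000. Positions are from GENCODE vM21 (GRCm38, the assembly of mm10), which held 95.3% of the identifiers. Each comparison was fitted to its own 4 libraries with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood fit and quasi-likelihood F test), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error (SE) of a log2 fold change was derived from the F statistic. The difference between the effects was the interaction in a fit of all 8 libraries with 4 group means. No control library was shared between the comparisons. Every adjusted p given for a gene comes from these edgeR fits and is two-sided.

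The tests, their alternatives, the 28 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 1 and a preset correlation of 0.01, adjusted over the 28 lists of a comparison. The named genes were the targeted and driver genes, the 10 largest rises and 10 largest falls past the threshold (groups without overlap, a mean of at least 10 CPM in the higher group, no predicted genes or pseudogenes), up to 4 members of each list that passed or held at least 3 called genes, the 5 genes with the smallest p for the difference, and the 3 members of each list of other cell types with the highest mean over all 8 libraries. Up to 4 members were named in the collagen, matricellular, contractile and Smad3 target lists in any case. The test of the difference for whole lists, with its alternatives, was added after the data were seen.

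The alternatives fixed in advance were size factors of the DESeq2 type, no low-count filter, DESeq2 1.42.0, a fit without robust estimation, a fit of all 8 libraries, an estimated correlation, fry, and leaving out each library in turn. In the last, the lone library of a group is assumed to vary like the other group. In the text, a call "lost without" a library had an adjusted p above 0.05 without it, and "up to" gives the highest adjusted p so reached. Unsummed entries, removal of a trend with transcript length (loess span 0.5) and a test without genes on chromosomes X and Y were chosen after seeing the data. The fits were tested on simulated counts in which 100 genes changed by each fold. Of the genes changed 2-fold, 37% were recovered in the Smad2/3 design, 28% in the Tgfbr1/2 design and 5% for the difference, against 88%, 92% and 63% of those changed 4-fold. Unchanged genes made up 9 of the 134 calls, 17 of 137 and 3 of 71. The share was thus above the threshold of 0.05 in both the Smad2/3 and the Tgfbr1/2 design, and larger in the latter. Changed genes were taken from those with a mean of at least 5 CPM, so recovery of lower genes was not measured. Each gene was drawn independently, so shifts that genes share within a library were left out. Library totals ran from 21477742 to 32594649 counts, so that 3 counts correspond to 0.092 to 0.14 CPM. Such floors cover counting error only, since amplified reads are not independent molecules. Libraries of 1 group differed by far more than sampling noise (chi-square per degree of freedom 36.2 to 77.8), and none was a copy of another. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.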

Results

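Gene expression was measured in cardiac fibroblasts sorted by a GFP reporter 4 weeks after transverse aortic constriction, a surgical narrowing of the aorta that puts the heart under pressure overload. The reporter marked cells in which Cre had acted under the control of Postn, a gene of activated fibroblasts, or Tcf21, a gene of resident fibroblasts. The 8 libraries formed 4 groups of 2. Postn-Cre control libraries (HK3 and HK4) were compared with Smad2/3 double knockout (DKO) libraries (HK15 and HK16), and Tcf21-Cre control libraries (HK6 and HK7) with Tgfbr1/2 DKO libraries (HK2 and HK4). Total counts were 25998890 and 22987700 in the Postn-Cre control libraries and 25529906 and 21477742 in the Smad2/3 DKO libraries. They were 29192032 and 29222803 in the Tcf21-Cre control libraries and 32594649 and 29936164 in the Tgfbr1/2 DKO libraries. Each comparison was sequenced in its own run with its own Cre driver, so run, driver and targeted genes change together between them. The labels do not say whether libraries came from separate animals or pools, and p-values measure only the spread between these libraries.

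The targeted genes were read first in every library. Smad2 (chromosome 18, 76241580 to 76310963) and Smad3 (chromosome 9, 63646767 to 63757994) encode the signal transducers downstream of the TGF-beta receptors. In the Postn-Cre control libraries, Smad2 was at 95.4 and 82.3 CPM and Smad3 at 114 and 92.7 CPM, against 84.5 and 78.2 CPM and 70.5 and 109 CPM in the Smad2/3 DKO libraries. The log2 fold changes were -0.19 ± 0.19 for Smad2 (SE; adjusted p = 0.747) and -0.26 ± 0.23 for Smad3 (adjusted p = 0.702). Tgfbr1 (chromosome 4, 47353222 to 47414931) and Tgfbr2 (chromosome 9, 116084293 to 116175360) encode the receptors. In the Tcf21-Cre control libraries they were at 229 and 238 CPM and at 370 and 406 CPM, against 181 and 193 CPM and 471 and 406 CPM in the Tgfbr1/2 DKO libraries. The log2 fold changes were -0.24 ± 0.19 (adjusted p = 0.533) and 0.25 ± 0.20 (adjusted p = 0.535). No loss of the targeted genes was therefore detected in their total counts. The labels do not say which exons are floxed, and counts over a whole gene cannot check the loss of single exons, so DKO is used here as the labels give it. Untargeted genes of the pathway also stayed short of the threshold, with Tgfbr1 at 0.45 (adjusted p = 0.223) and Tgfbr2 at -0.32 (adjusted p = 0.366) in the Smad2/3 comparison. In the Tgfbr1/2 comparison, Smad2 was at -0.03 (adjusted p = 0.948) and Smad3 at -0.27 (adjusted p = 0.421). The driver gene Postn had log2 fold changes of 0.50 (adjusted p = 0.157) and -0.41 (adjusted p = 0.563) in the 2 comparisons, and Tcf21 of 0.37 (adjusted p = 0.589) and -0.04 (adjusted p = 0.939).

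The first comparison set libraries labelled Smad2/3 DKO against their controls, in activated fibroblasts of the overloaded heart. Collagen genes fell together in the Smad2/3 DKO libraries: 12 of 19 measured chains fell, none rose and 7 did not pass the test. Col3a1 and Col1a1, chains of the main fibrillar collagens, fell by 2.15 ± 0.15 (adjusted p = 7.89e-05) and by 1.69 ± 0.17 (adjusted p = 0.00108) on the log2 scale, with n = 2 libraries per group. Col3a1 went from 5130 and 4307 CPM to 1067 and 1147 CPM, and Col1a1 from 1574 and 1480 CPM to 564 and 422 CPM. Adam12, a membrane metalloprotease of activated fibroblasts, was at 24.2 and 26.6 CPM in the controls and at 1.76 and 2.37 CPM in the DKO libraries (-3.67 ± 0.38, adjusted p = 0.00146). Col3a1 (ENSMUSG00000026043) lies on chromosome 1 at 45311538 to 45349706, Col1a1 (ENSMUSG00000001506) on chromosome 11 at 94936224 to 94953042, and Adam12 (ENSMUSG00000054555) on chromosome 7 at 133883199 to 134232146. In all, 206 of 15760 tested genes passed the threshold, 71 higher and 135 lower, and 2139 had an unadjusted p below 0.05. The count was 102 without DKO HK15. Without control HK3 it was 243, of which 47.7% were higher, against 34.5% of the 206.

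Col1a2 (-1.44 ± 0.14, adjusted p = 0.00108) and Col6a1 (-1.32 ± 0.17, adjusted p = 0.00365) were the other leading collagen chains. Adjusted over the list alone, 15 chains fell. The collagen list passed its test (median log2 fold change -1.03, adjusted p = 1.21e-10), and did so without each of the 4 libraries in turn, but had an adjusted p = 0.735 with an estimated correlation. Of 40 matricellular and matrix glycoprotein genes, 10 fell and 30 did not pass (14 fell and 2 rose adjusted over the list alone), with a list median of -0.31 (adjusted p = 0.00975, and adjusted p = 0.735 with an estimated correlation). Among them were fibronectin (Fn1, -1.09 ± 0.14, adjusted p = 0.00365), fibrillin-1 (Fbn1, -1.25 ± 0.17, adjusted p = 0.00442), tenascin-C (Tnc, -1.23 ± 0.17, adjusted p = 0.00489) and Sparc, a collagen-binding protein (-2.05 ± 0.27, adjusted p = 0.00442). Of 23 collagen processing genes, 2 fell and 21 did not pass (5 fell and 1 rose adjusted over the list alone). Loxl2, which crosslinks collagen, fell by 1.31 ± 0.14 (adjusted p = 0.00187) and Adamts2, which trims procollagen, by 0.93 (adjusted p = 0.0456), while Fkbp10 was at -1.45 (adjusted p = 0.0887) and Tgm2 at -0.72 (adjusted p = 0.126). Of 23 matrix proteases and inhibitors, 1 rose, 2 fell and 20 did not pass (1 rose and 10 fell adjusted over the list alone). Besides Adam12, the protease Adamts9 fell by 0.84 (adjusted p = 0.0388), Mmp3 rose by 2.54 (adjusted p = 0.0276) and Ctsk was at -1.27 (adjusted p = 0.0642). The processing and protease lists had adjusted p = 0.025 and 0.0415, and adjusted p = 0.735 with an estimated correlation for both. Without control HK3 the adjusted p was 0.305 for the matricellular, 0.305 for the processing and 0.382 for the protease list, and without DKO HK16 it was 0.139, 0.184 and 0.133. The protease list also lost its call without DKO HK15 (adjusted p = 0.112). Sparc lost its call without HK3 and HK4 (up to adjusted p = 0.293). Adamts2 and Adamts9 lost theirs without HK3, HK15 and HK16 (up to 0.187 and 0.208). Mmp3 lost its call without HK16 (0.0569), and its log2 value was 1.95 without HK3 and 3.54 without HK4.

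**Figure D1:**
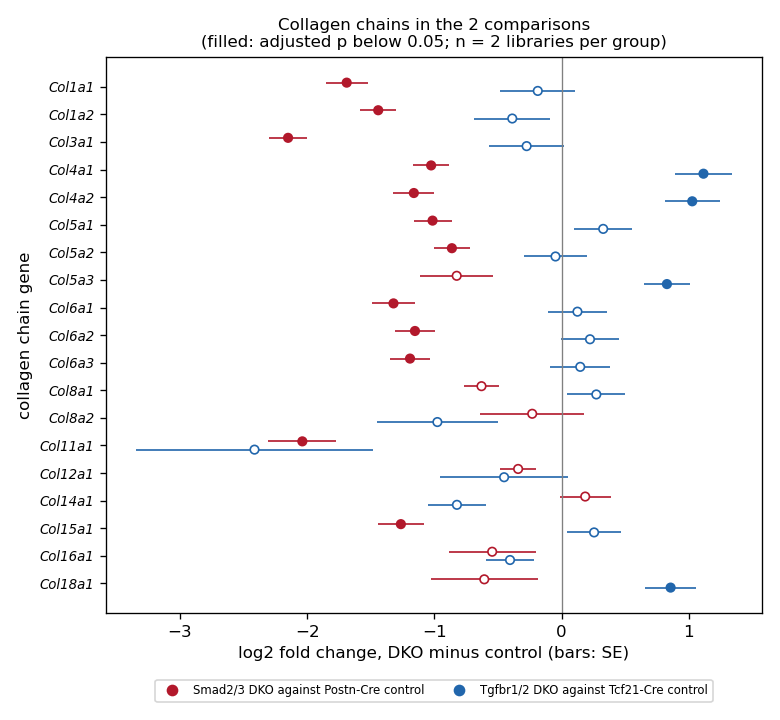
Log2 fold change (DKO minus control, horizontal axis) of 19 collagen chain genes in both comparisons: points are edgeR estimates, bars their SE, and filled points passed an adjusted p of 0.05 (n = 2 libraries per group). The 12 filled points of the Smad2/3 comparison lie below 0 and the 4 of the Tgfbr1/2 comparison above 0.

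Genes of myofibroblast contraction and the cytoskeleton did not pass as a list in the Smad2/3 comparison (0 of 31 called, adjusted p = 0.187; 1 fell adjusted over the list alone). Cald1 was at -0.61 (adjusted p = 0.076), Itgb5 at 0.77, Flna at -0.48 and Itga5 at -0.40. Of 28 genes chosen as TGF-beta and Smad3 targets, 3 fell and 25 did not pass (6 rose and 4 fell adjusted over the list alone; list adjusted p = 0.831). The 3 were Col1a1, Adam12 and Angptl4, a secreted inhibitor of lipoprotein lipase (-2.17 ± 0.36, adjusted p = 0.0156; 0.0691 without DKO HK15), and Snai2 was at -1.20 (adjusted p = 0.0505). Of 12 BMP and Smad1/5 target genes none was called (1 rose adjusted over the list alone), with Id3 at 0.99 (adjusted p = 0.0771), Bambi at 0.88, Smad6 at 1.29 and Atoh8 at 1.78. As a list they rose (median 0.59, adjusted p = 0.0415; adjusted p = 0.735 with an estimated correlation, 0.251 without control HK4 and 0.292 without DKO HK16). Of 24 resting fibroblast genes, 2 rose and 2 fell (4 rose and 7 fell adjusted over the list alone; list adjusted p = 0.588). Dpep1, a membrane dipeptidase, rose by 1.97 ± 0.22 (adjusted p = 0.00194) and Lpl, lipoprotein lipase, fell by 1.27 ± 0.17 (adjusted p = 0.00459). Cd248 was at -1.64 and lost its call without HK3, HK15 and HK16 (up to 0.0602), and Dkk3 was at 0.85 and lost its call without HK4 and HK15 (up to 0.166).

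Of 24 cytokine, chemokine and NF-kB genes, 6 rose and 1 fell in the Smad2/3 DKO libraries (10 rose and 6 fell adjusted over the list alone; list adjusted p = 0.244). The chemokines Ccl7 (1.73 ± 0.25, adjusted p = 0.00662) and Cxcl16 (1.19 ± 0.17, adjusted p = 0.00572) and the NF-kB inhibitor Nfkbia (1.38 ± 0.20, adjusted p = 0.0071) rose, and the interleukin receptor Il1r1 fell by 1.06 (adjusted p = 0.00521; 0.0665 without DKO HK15). Of 30 growth factors and IGF binding proteins, 1 rose and 4 fell (2 rose and 4 fell adjusted over the list alone; list adjusted p = 0.588). Igfbp3 rose by 1.62 ± 0.23 (adjusted p = 0.00532), Angptl2 fell by 1.02 (up to 0.0689, lost without HK15 and HK16) and Fgf1 fell by 1.76 (up to 0.133, lost without HK3, HK15 and HK16). Interferon-response genes fell as a list (median -0.52 over 26 genes, 0 called; 5 fell adjusted over the list alone; adjusted p = 0.013, and 0.735 with an estimated correlation), with B2m at -0.73 (adjusted p = 0.0569), Ifi27l2a at -1.81, Ifi44 at -2.10 and Oasl2 at -0.97. Immediate early and dissociation stress genes rose as a list (median 0.45 over 26 genes, 1 rose and 1 fell; 8 rose and 1 fell adjusted over the list alone; adjusted p = 0.013, and 0.735 with an estimated correlation). Egr1 rose by 0.71 (up to 0.148, lost without HK4, HK15 and HK16) and Klf6 fell by 0.79 (adjusted p = 0.186 without HK15), beside Ier3 at 0.89 and Nr4a1 at 1.11. The interferon list lost its call without HK3 (0.916) and HK16 (0.139), and the immediate early list without HK4 (0.251) and HK15 (0.159).

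Markers of other cell types moved in the same comparison. Endothelial markers were lower as a list in the Smad2/3 DKO libraries (median -1.10 over 20 genes, 0 called; 1 fell adjusted over the list alone; adjusted p = 0.00401, and 0.735 with an estimated correlation). Cardiomyocyte markers were lower too (median -1.11 over 19 genes, 0 called, and 0 adjusted over the list alone; adjusted p = 0.00601, and 0.735 with an estimated correlation). Eng was at 84.8 and 72.9 CPM in the controls and 50.8 and 36.4 CPM in the DKO libraries, Tek at 124, 77.7, 76.1 and 71.4 CPM, Cav1 at 82.0, 48.4, 38.1 and 37.0 CPM. Esam and Tie1 had log2 fold changes of -2.09 and -1.92. The cardiomyocyte markers with the highest means over all 8 libraries, Atp2a2, Ttn and Actc1, were at 451, 95.3 and 44.1 CPM in control HK3 and 534, 136 and 14.1 CPM in control HK4. They were at 634, 63.1 and 12.3 CPM in DKO HK15 and 582, 82.3 and 2.98 CPM in DKO HK16. Myh6 was at -1.21 and Tnni3 at -2.20. Without control HK3 the adjusted p was 0.375 for both lists, and without DKO HK16 it was 0.133 for the endothelial list. Of 14 pericyte and smooth muscle markers, 1 fell (1 adjusted over the list alone; list adjusted p = 0.0701). Rgs5 was at 1201, 607, 730 and 543 CPM, Pdgfrb at 110, 76.2, 131 and 84.1 CPM and Steap4 at 75.7, 52.0, 58.8 and 69.6 CPM in HK3, HK4, HK15 and HK16.

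Outside the lists, the largest rises in the Smad2/3 DKO libraries were those of Gabra3, a GABA receptor subunit on chromosome X (8.01 ± 0.40, adjusted p = 4.18e-06; 8.62 without control HK3), which went from 0.35 and 0.17 CPM to 65.5 and 79.5 CPM. Art4 went from 0.231 and 0.218 CPM to 12.3 and 10.8 CPM (adjusted p = 0.00162). Fmo2 (3.96 ± 0.21, adjusted p = 4.87e-06), and the splicing factor gene Cwc22 (3.59 ± 0.17, adjusted p = 4.18e-06) rose. Gabre (3.57 ± 0.43, adjusted p = 0.00312), Ang (3.55 ± 0.36, adjusted p = 0.00139), Galntl2 (2.34 ± 0.33, adjusted p = 0.00572) and Kcnj15 (2.23 ± 0.19, adjusted p = 0.000523) also rose. Xist, the RNA that silences 1 X chromosome in female cells, was at 3.65 and 2.18 CPM in the controls and 277 and 75.3 CPM in the DKO libraries (5.84, adjusted p = 0.00459), a call lost without HK3 (0.405) and HK4 (0.546). Its log2 value was 4.63 without HK15 and 6.49 without HK16. The Y-linked genes Ddx3y (132 and 177 CPM) and Kdm5d (37.3 and 30.4 CPM) were also present in the DKO libraries. The sex make-up of the groups may therefore differ, which cannot be told apart from genotype in this comparison. Besides Adam12, the largest falls that stood without each library were those of the receptor gene Gpr39 (-2.60, adjusted p = 0.00139), the proliferation marker Mki67 (-2.50, adjusted p = 0.0172; -3.39 without HK15), Gfra2 (-2.27; -3.07 without HK15) and D0H4S114 (-2.27). Kcnj8 (-3.17; lost without HK3, 0.0606) and Slc7a11 (-2.74; lost without HK15 and HK16, up to 0.688) fell in the fit of all 4 libraries. So did Sdk1 (-2.44; without HK3 and HK15, up to 0.0684), Slitrk2 (-2.41; without HK3 and HK15, up to 0.131) and Mgam (-2.35; without HK3, HK15 and HK16, up to 0.181). Without 1 library, Kcnj8 reached -2.49 (HK3) and -4.02 (HK15), and Slc7a11 -1.69 (HK4) and -3.34 (HK3). Cwc22 and Ang have close copies in the genome, so their values depend on how shared reads were counted.

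The remaining lists did not pass in the Smad2/3 comparison. Their adjusted p were 0.0605 for Wnt pathway genes (2 of 23 rose), 0.17 for proteoglycans (2 of 18 fell), 0.187 for epicardial and mesothelial markers, 0.244 for myeloid and for Schwann cell markers and 0.401 for cell cycle genes (1 of 34 fell) and for cartilage and bone matrix genes. They were 0.447 for the TGF-beta superfamily (1 of 36 fell), 0.505 for complement genes (1 of 14 rose), 0.831 for adipogenic genes (1 of 12 fell), 0.889 for glycolysis genes, 0.963 for erythroid markers and 0.998 for lymphocyte markers. Adjusted over the list alone, Wnt genes counted 4 risen and 0 fallen, proteoglycans 2 and 4, epicardial markers 0 and 2, and cell cycle genes 1 and 3. The counts were for the superfamily 4 and 4, complement genes 1 and 0, adipogenic genes 0 and 1, cartilage genes 1 and 0 and lymphocyte markers 0 and 1, and the remaining ones 0 and 0. Median and mean differed in sign for cartilage (0.02 and -0.36), glycolysis (-0.07 and 0.05) and lymphocyte genes (0.47 and -0.16). Of the markers with the highest means over all 8 libraries, in the order HK3, HK4, HK15 and HK16, Lyz2 was at 3.15, 1.09, 1.96 and 0.56 CPM, Cd74 at 11.2, 2.13, 5.17 and 2.14 CPM and Cd68 at 9.46, 22.1, 14.4 and 12.5 CPM (myeloid). Aldh1a2 was at 39.4, 35.1, 13.7 and 17.7 CPM, Tbx18 at 22.9, 24.8, 24.8 and 18.4 CPM and Wt1 at 7.27, 0.74, 0.82 and 0.23 CPM (epicardial). Cdh19 was at 17.4, 20.2, 31.4 and 22.2 CPM, and Kcna1 and Ngfr stayed below 10 CPM in every library (Schwann cell). The lymphocyte markers Cd4, Cd79a and Cd8a did too, while Hba-a1 was at 12.1, 1.70, 3.33 and 4.80 CPM and Hbb-b1 and Hbb-b2 stayed below 10 CPM.

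In the authors' deposited table, Col1a1 is listed at -1.645, Col3a1 at -2.087, Adam12 at -1.615 and Angptl4 at -2.117 on the log2 scale. The value for Adam12 is smaller in size than the -3.67 of the edgeR fit. Of the 206 called genes, 204 have the same sign there, and the Spearman correlation across 15760 genes was 0.793. Both sets of values come from the same libraries, so their likeness is not independent evidence.

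The second comparison set libraries labelled Tgfbr1/2 DKO against their controls, in the Tcf21 lineage under the same load. The type I and III collagen chains did not pass the test in the Tgfbr1/2 DKO libraries (Col1a1 -0.19 ± 0.29, adjusted p = 0.777; Col3a1 -0.28 ± 0.30, adjusted p = 0.658; Col1a2 -0.39 ± 0.30, adjusted p = 0.517), and no collagen chain of 19 fell. Timp1, an inhibitor of matrix proteases, rose by 3.03 ± 0.23 (adjusted p = 0.000122), from 104 and 123 CPM to 938 and 829 CPM, and tenascin-C (Tnc) by 2.54 ± 0.27 (adjusted p = 0.00126), from 183 and 267 CPM to 1164 and 1310 CPM. Adam12 (2.42 ± 0.23, adjusted p = 0.000491) and Angptl4 (3.08 ± 0.21, adjusted p = 7.39e-05) rose, with n = 2 libraries per group. Timp1 (ENSMUSG00000001131) lies on chromosome X at 20870166 to 20874735, Tnc (ENSMUSG00000028364) on chromosome 4 at 63959785 to 64047015, and Angptl4 (ENSMUSG00000002289) on chromosome 17 at 33773750 to 33781830. In all, 657 of 16658 tested genes passed the threshold, 439 higher and 218 lower, and 3332 had an unadjusted p below 0.05. The count was 316 without control HK7, 341 without DKO HK2 and 272 without DKO HK4.

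Of the collagen chains, 4 rose and 15 did not pass (4 rose and 1 fell adjusted over the list alone; list median 0.12, mean -0.04, adjusted p = 0.568). The 4 were Col4a1 (1.11, adjusted p = 0.025), Col4a2 (1.03, adjusted p = 0.0284), Col5a3 (0.83, adjusted p = 0.0333) and Col18a1 (0.86, adjusted p = 0.0447). Col4a1 and Col18a1 lost their calls without HK7, HK2 and HK4 (adjusted p up to 0.113 and 0.179), and Col4a2 and Col5a3 without any 1 of the 4 libraries (up to 0.125 and 0.163). Of 40 matricellular genes, 2 rose and 3 fell (5 rose and 5 fell adjusted over the list alone; list median -0.02, adjusted p = 0.756 in the upward direction). Besides Tnc these included Wisp2 (-1.29 ± 0.21, adjusted p = 0.00958), Tgfbi, a matrix protein named for its induction by TGF-beta (-1.07, adjusted p = 0.0163), and Efemp2 (0.94, adjusted p = 0.0207). Of 18 proteoglycans, 1 rose and 4 fell (3 rose and 5 fell adjusted over the list alone; list adjusted p = 0.568), among them Ogn (-1.47, adjusted p = 0.0145), Gpc6 (-1.08), Omd (-1.32) and the lubricant Prg4 (1.30, adjusted p = 0.0222). Tgfbi, Gpc6 and Omd lost their calls without HK7, HK2 and HK4 (up to 0.0955, 0.11 and 0.126), Ogn and Prg4 without HK7 and HK4 (up to 0.0761 and 0.128), and Efemp2 without any 1 of the 4 (up to 0.0807).

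Of 23 collagen processing genes, 5 rose and 18 did not pass in the Tgfbr1/2 DKO libraries (8 rose adjusted over the list alone; list median 0.44, adjusted p = 0.000393, and 0.774 with an estimated correlation), among them Plod3 (1.06), Tgm2 (1.08), Serpinh1 (1.04) and Glt25d1 (0.85). Of 22 matrix proteases and inhibitors, 6 rose and 16 did not pass (8 rose adjusted over the list alone; list median 0.50, adjusted p = 0.00134, and 0.774 with an estimated correlation). Among those that rose were Timp1, Adam12, urokinase (Plau, 1.75 ± 0.21, adjusted p = 0.00224) and stromelysin (Mmp3, 3.15 ± 0.40, adjusted p = 0.00323). Of 31 contractile and cytoskeletal genes, 7 rose and 24 did not pass (11 rose and 1 fell adjusted over the list alone; list median 0.36, adjusted p = 0.000787, and 0.774 with an estimated correlation). The smooth muscle actin gene Acta2, a marker of myofibroblasts, rose by 1.09 ± 0.19 (adjusted p = 0.0141), the fibronectin receptor subunit Itga5 by 1.55 ± 0.24 (adjusted p = 0.00882), Cnn2 by 1.00 and Tpm4 by 1.05. Itga5 lost its call without HK7 (0.0613), Acta2 without HK7 and HK4 (up to 0.0819), Cnn2 without HK6, HK7 and HK2 (up to 0.108). Tpm4 and Plod3 lost theirs without HK6, HK7 and HK4 (up to 0.173 and 0.0949), Tgm2 without HK7 and HK4 (up to 0.0922), and Serpinh1 and Glt25d1 without any 1 of the 4 (up to 0.107 and 0.164). Of 28 TGF-beta and Smad3 target genes, 3 rose and 1 fell (4 rose and 2 fell adjusted over the list alone; list median -0.14, mean 0.12, adjusted p = 0.979). Angptl4, Timp1 and Adam12 rose and Tgfbi fell.

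**Figure D2:**
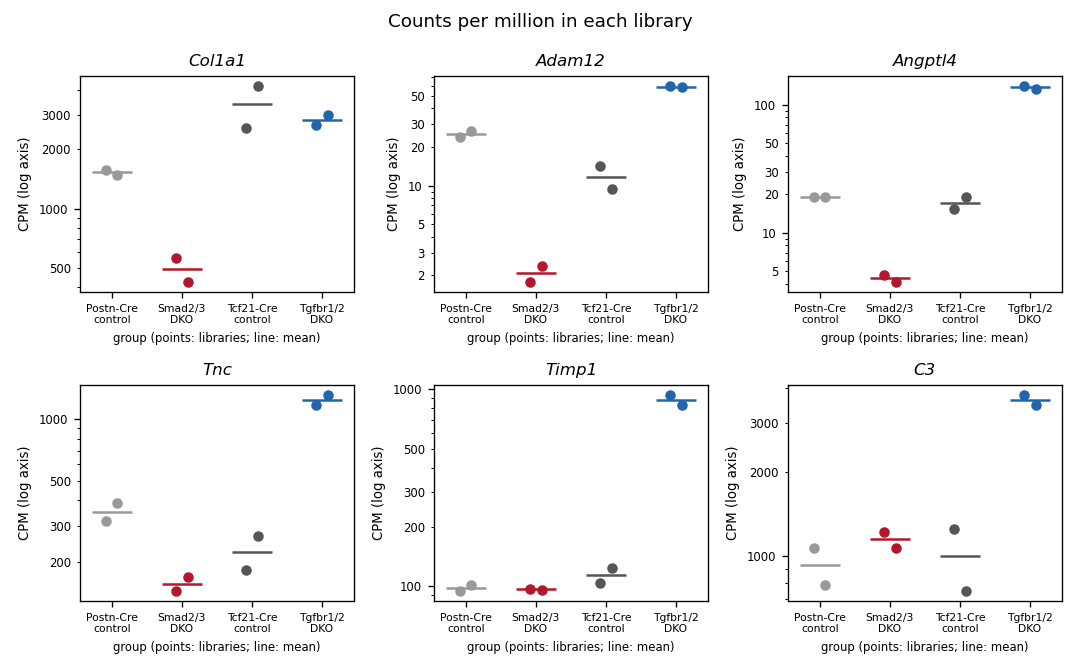
CPM in each library (vertical axis, log scale) for 6 genes in the 4 groups; points are libraries and lines are group means. Adam12, Angptl4 and Tnc lie below their controls in the Smad2/3 DKO libraries and above them in the Tgfbr1/2 DKO libraries, Col1a1 lies below its controls in the Smad2/3 DKO libraries, and Timp1 and C3 lie above their controls in the Tgfbr1/2 DKO libraries.

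Cytokine, chemokine and NF-kB genes rose as a list in the Tgfbr1/2 DKO libraries (3 of 28 rose, 25 did not pass; 5 rose adjusted over the list alone; median 0.82, adjusted p = 0.000106, and 0.774 with an estimated correlation). Lcn2, an acute-phase protein that binds bacterial iron carriers, rose by 4.30 ± 0.30 (adjusted p = 8.23e-05), the chemokine Cxcl12 by 1.65 ± 0.20 (adjusted p = 0.00278), and serum amyloid Saa3 went from 0.79 and 0.10 CPM to 14.5 and 13.2 CPM (adjusted p = 0.00866). Saa3 had a log2 value of 5.04, of 7.05 without HK6 and of 4.27 without HK7. Of 15 complement genes, 3 rose and 2 fell (7 rose and 3 fell adjusted over the list alone; list adjusted p = 0.114). The central component C3 rose by 1.96 ± 0.27 (adjusted p = 0.00526), from 1251 and 748 CPM to 3796 and 3485 CPM. C2 rose by 1.83 ± 0.26 (adjusted p = 0.00628), C7 fell by 1.39 ± 0.20 (adjusted p = 0.00708) and C1qtnf2 fell by 1.20 (lost without HK7 and HK2, up to 0.092). Glycolysis and hypoxia genes rose as a list (6 of 22 rose; 10 adjusted over the list alone; median 0.57, adjusted p = 0.00078, 0.774 with an estimated correlation and 0.108 without DKO HK4). The glycolytic enzyme genes Eno1 (1.71 ± 0.19, adjusted p = 0.00149), Pgk1 (1.38 ± 0.21, adjusted p = 0.00882; 0.0577 without HK7), Ldha (1.08; lost without HK6, HK7 and HK4, up to 0.13) and Aldoa (0.93; lost without any 1 of the 4, up to 0.165) rose. Adipogenic genes rose as a list (3 of 12 rose; 4 adjusted over the list alone; median 0.42, adjusted p = 0.0155, and 0.774 with an estimated correlation), with Pparg at 1.90, Fabp4 at 1.06 and Cd36 at 0.75. Pparg and Cd36 lost their calls without any 1 of the 4 libraries (up to 0.141 and 0.231) and Fabp4 without HK6, HK2 and HK4 (up to 0.111). Plin2 was at 0.76. Cell cycle genes rose as a list (2 of 36 rose, also adjusted over the list alone; median 0.28, adjusted p = 0.0312, 0.774 with an estimated correlation, 0.358 without HK7 and 0.194 without HK4). Mcm2 was at 1.59 (lost without HK6, HK2 and HK4, up to 0.0671), Ccnd1 at 1.55 (lost without HK7, HK2 and HK4, up to 0.136), Pcna at 0.57 and Ube2c at 0.73.

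Markers of other cell types moved in this comparison too. Macrophage and myeloid markers rose as a list in the Tgfbr1/2 DKO libraries (7 of 21 rose and 14 did not pass; 15 rose adjusted over the list alone; median 1.86, adjusted p = 4.6e-09, and 0.774 with an estimated correlation). Lyz2 was at 9.90 and 26.6 CPM in the controls and 82.5 and 90.6 CPM in the DKO libraries (adjusted p = 0.103), Cd74 at 12.7, 22.2, 43.7 and 57.1 CPM and Cd68 at 22.1, 13.8, 18.4 and 15.5 CPM in HK6, HK7, HK2 and HK4. Cd163 (3.89), Itgam (1.72), Cd14 (1.86) and Cd74 (1.61) rose. Cd163 lost its call without HK6, HK7 and HK2 (up to 0.115), Itgam without HK7, HK2 and HK4 (up to 0.0858), and Cd14 and Cd74 without HK6 and HK4 (up to 0.0935 and 0.102). Endothelial markers rose as a list (4 of 20 rose; 7 rose and 2 fell adjusted over the list alone; median 0.58, adjusted p = 0.00228, and 0.774 with an estimated correlation). Ly6c1 rose by 1.69 ± 0.19 (adjusted p = 0.00138), and Eng (0.78), Cav1 (0.82) and Gpihbp1 (1.41) rose with calls lost without any 1 of the 4 libraries (up to 0.167, 0.235 and 0.16). Eng was at 190, 172, 311 and 279 CPM, Tek at 163, 124, 88.1 and 81.8 CPM, and Cav1 at 73.6, 70.4, 114 and 125 CPM. Epicardial and mesothelial markers rose as a list (3 of 7 rose; 5 adjusted over the list alone; median 3.14, adjusted p = 0.0045, and 0.774 with an estimated correlation). Aldh1a2, which makes retinoic acid, was at 49.3 and 16.5 CPM in the controls and 387 and 420 CPM in the DKO libraries (3.73 ± 0.53, adjusted p = 0.0295), a call lost without HK2 (0.288) and HK4 (0.286), with a log2 value of 4.65 without HK6. Lrrn4 had no count in the controls and 1.78 and 0.80 CPM in the DKO libraries, at least 12.5-fold higher against a floor of 3 counts per library, and its call was lost without HK7 (0.0613) and HK2 (0.0824). The list median was 3.14 with Lrrn4 at that bound. Gpm6a, with 2 counts in the controls together, was at 0.0685 and 0 CPM there and at 0.92 and 1.00 CPM in the DKO libraries (adjusted p = 0.0428), a call lost without any 1 of the 4 libraries (up to 0.202). Msln was at 3.14 (adjusted p = 0.0991), Tbx18 at 32.2, 27.8, 33.5 and 22.2 CPM and Wt1 at 1.61, 1.54, 0.98 and 0.67 CPM. Only 7 of the 14 epicardial and mesothelial members passed the low-count filter and were tested. Lrrn4, Gpm6a and Msln (0.07 and 0.14 CPM in the controls, 1.35 and 0.47 CPM in the DKO libraries) passed it only through the DKO libraries. Such a filter favours a rise, so the median and the call of this list may be too high. Cardiomyocyte markers were not called (median 0.02 over 21 genes, adjusted p = 0.671), with Atp2a2 at 396, 325, 439 and 421 CPM, Ttn at 93.6, 106, 86.1 and 47.8 CPM and Actc1 at 15.9, 30.9, 64.8 and 42.8 CPM.

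Outside these lists, the protease inhibitor genes Serpina3m (7.53 ± 0.32, adjusted p = 3.54e-06) and Serpina3g (4.88 ± 0.27, adjusted p = 2.15e-05), the glucuronosyltransferase genes Ugt1a6b (5.07 ± 0.32, adjusted p = 4.72e-05) and Ugt1a6a (3.87), and Lect1 (3.98 ± 0.39, adjusted p = 0.000643) rose most in the Tgfbr1/2 DKO libraries. Serpinb2 went from 0.14 and 0 CPM to 22.7 and 13.6 CPM (adjusted p = 0.000398), and Ifi202b from 0.14 and 0 CPM to 12.9 and 11.2 CPM (adjusted p = 0.000339). With 4 counts in their controls, their fitted log2 values moved from 8.03 and 7.46 to 12.12 and 11.54 without HK6, and to 7.13 and 6.55 without HK7. Rab6b (chromosome 9, 103111787 to 103185276), a vesicle transport gene, fell by 4.61 ± 0.33 (adjusted p = 0.000214), from 91.8 and 50.7 CPM to 2.36 and 3.07 CPM. Gal3st2 (-4.16 ± 0.45, adjusted p = 0.00187), Col4a3, a basement membrane collagen outside the collagen list (-2.71 ± 0.24, adjusted p = 0.000339), Cap2 (-2.73; -3.34 without HK4), and Dzank1 (-2.58) fell. Zfp949 (-2.51; -1.90 without HK6), Ccdc3 (-2.31), the semaphorin Sema3d (-2.00) and Gpr39 (-1.93) fell too. Heatr7b1 fell by 1.91 with a call lost without HK7 (log2 value -1.33, adjusted p = 0.0917) and HK4 (0.0705). The Serpina3, Ugt1a, Ifi202 and Ly6 genes belong to families with near-identical or overlapping members, and Eno1 and Pgk1 have close copies, so their values are uncertain where reads were shared. Among resting fibroblast genes, 3 of 24 rose and 1 fell (3 rose and 2 fell adjusted over the list alone; list adjusted p = 0.568). The chemokine Cxcl14 (1.96 ± 0.20, adjusted p = 0.000986), the progenitor marker Ly6a (1.44 ± 0.21, adjusted p = 0.00664) and Dpep1 (1.34, adjusted p = 0.00951; 0.0566 without HK7) rose, and Dkk3 fell by 1.03 (lost without HK7, HK2 and HK4, up to 0.209).

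Of the remaining lists in the Tgfbr1/2 comparison, growth factors (2 of 30 rose and 2 fell; 3 and 2 adjusted over the list alone) had adjusted p = 0.671. Among them, Angpt2 was at -1.53 (lost without 3 libraries, up to 0.0999), Angpt1 at -0.95 (lost without any 1 of the 4, up to 0.252) and Figf at 0.98 (lost without HK7 and HK2, up to 0.23). Immediate early and dissociation stress genes (1 of 26 rose and 2 fell, also adjusted over the list alone) had adjusted p = 0.671. The heat shock genes were at -1.62 for Hspa1a (adjusted p = 0.0147), -1.59 for Hspa1b (lost without HK2, 0.094) and 0.87 for Hspb1 (lost without HK6, HK2 and HK4, up to 0.21). The others had adjusted p of 0.051 for erythroid markers (2 rose adjusted over the list alone), 0.0668 for Schwann cell markers, 0.16 for interferon-response genes, and 0.162 for pericyte and smooth muscle markers. They were 0.568 for BMP targets and for Wnt genes (2 of 26 fell, also adjusted over the list alone), 0.764 for lymphocyte markers, 0.886 for the TGF-beta superfamily (2 of 37 rose, also adjusted over the list alone) and 0.936 for cartilage and bone matrix genes. The superfamily had a median of -0.02 and a mean of 0.02, and the cartilage list a median of -0.04 with a test in the upward direction. Pdgfrb was at 283, 342, 374 and 339 CPM, Rgs5 at 434, 222, 191 and 260 CPM and Steap4 at 178, 36.2, 262 and 242 CPM in HK6, HK7, HK2 and HK4 (pericyte). The Schwann cell marker Cdh19 was at 30.9 and 13.3 CPM in HK6 and HK7 and at 14.97 and 10.6 CPM in HK2 and HK4. Kcna1 and Ngfr and the lymphocyte markers Cd4, Cd79a and Cd8a stayed below 10 CPM in every library. The erythroid markers Hbb-b1, Hbb-b2 and Hba-a1 were at 8.19, 6.78 and 4.93 CPM in HK6, 15.5, 12.5 and 7.36 CPM in HK7, 47.4, 37.6 and 23.4 CPM in HK2 and 17.6, 12.5 and 8.42 CPM in HK4. In the authors' deposited table, Col1a1 is listed at -0.221, Adam12 at 2.363, Angptl4 at 3.011 and Timp1 at 2.962 on the log2 scale. Of the 657 called genes, 625 have the same sign there, and the Spearman correlation across 16658 genes was 0.795, from the same libraries.

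The effects of the 2 knockouts were then set against each other. The genes with the smallest p for the difference were Angptl4 (-5.25 ± 0.31), Cwc22 (3.86 ± 0.24), Gabra3 (9.17 ± 0.58; 9.79 without HK3) and Adam12 (-6.11 ± 0.39), each with adjusted p = 3.15e-05, and Rab6b (6.03 ± 0.43, adjusted p = 7.33e-05). A negative value is a lower effect in the Smad2/3 comparison. In all, 326 of 17770 genes passed for the difference, 118 with a higher and 208 with a lower effect in the Smad2/3 comparison. The count fell to 175, 170, 95, 156, 135 and 89 without control HK3, DKO HK15, DKO HK16, control HK7, DKO HK2 and DKO HK4. Col3a1 differed (-1.88 ± 0.37, adjusted p = 0.0314; lost without control HK3, DKO HK15, DKO HK16 and Tgfbr1/2 DKO HK4, up to 0.0951), while Col1a1 did not pass (-1.51 ± 0.38, adjusted p = 0.0751). Across 15017 genes tested in both, the fold changes had a Spearman correlation of -0.076 and a Pearson correlation of -0.068, with genes not being independent replicates. The Spearman value was -0.022 without control HK3, -0.123 without Postn-Cre control HK4, -0.034 without control HK7 and -0.027 without Tgfbr1/2 DKO HK4. Of the genes called in both, 10 were higher in the Smad2/3 and lower in the Tgfbr1/2 comparison, against 0.87 for independent lists (Fisher's exact test, adjusted p = 5.76e-08), among them Art4, Ang, Sema3d, Dkk3, Rab6b and the imprinted gene Peg3. The overlap was 5 against 3.54 for genes lower in the first and higher in the second (adjusted p = 0.408), which were Adam12, Angptl4, Col4a1, Col4a2 and Tnc. It was 5 against 1.68 for genes higher in both (Creld2, Dpep1, Manf, Mmp3 and Serpina3n; adjusted p = 0.0348). It was 6 against 1.84 for genes lower in both (Col4a3, D0H4S114, Fndc1, Gpr39, Itih5 and Tpm3-rs7; adjusted p = 0.0211). All 4 overlaps were tested with Fisher's exact test and adjusted together. The test treats genes as independent, which they are not, so these p-values may be too small. The overlaps were not recomputed with libraries left out. Run, Cre driver and targeted genes cannot be told apart in any of these differences.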

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

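The results below are those in which the effects of the 2 knockouts differed by the interaction test; of the tests of explanations, the one on a further macrophage gene set was planned before its result was seen, and all others, with the tests of the difference for whole lists, were chosen after.

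The difference passed for 56 named genes that were called in at least 1 comparison (adjusted p 3.15e-05 to 0.046). These genes were named for large changes or small p in these same data. Such a choice favours a difference and can inflate its size, so the number 56 is not a rate. The values are the log2 fold change in the Smad2/3 comparison minus that in the Tgfbr1/2 comparison. It was below 0 for Angptl4 (-5.25), Adam12 (-6.11), Timp1 (-3.12), Tnc (-3.77), Aldh1a2 (-5.04), Serpina3g (-4.05), Ugt1a6b (-5.56), Ugt1a6a (-3.99), Eno1 (-2.46), Col4a1 (-2.15), Col4a2 (-2.20), Cxcl12 (-2.71), Serpinb2 (-11.86), Cd248 (-2.17), Sdk1 (-3.21), Loxl2 (-1.75), Ifi202b (-8.14), Itga5 (-1.96), Col5a3 (-1.66) and Eng (-1.71). It was also below 0 for Saa3 (-9.35), Ly6a (-2.67), Tgm2 (-1.81), Flna (-1.44), Fkbp10 (-2.30), Lcn2 (-5.37), Mgam (-3.23), Kcnj8 (-3.89), Fbn1 (-1.68), Ccnd1 (-2.70), Serpina3m (-7.37), Col3a1 (-1.88), C3 (-1.73), Cav1 (-1.69), Col6a1 (-1.45), C2 (-2.84), Il1r1 (-1.86), Pgk1 (-1.37), Angptl2 (-1.21) and Ly6c1 (-2.41). It was above 0 for Cwc22 (3.86), Gabra3 (9.17), Rab6b (6.03), Fmo2 (3.37), Sema3d (3.34), Art4 (7.20), Kcnj15 (3.02), Ang (5.01), Xist (6.18), Gabre (4.37), Gal3st2 (5.09), Dkk3 (1.87), Ogn (2.01), Omd (2.15), Gpc6 (1.43) and Wisp2 (2.06).

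With each of the 8 libraries left out in turn, 27 of the 56 genes kept the call throughout and 29 lost it at least once. The number lost was 16 without control HK3, 5 without Postn-Cre control HK4, 12 without Smad2/3 DKO HK15, 26 without Smad2/3 DKO HK16, 6 without control HK6, 14 without control HK7, 12 without Tgfbr1/2 DKO HK2 and 23 without Tgfbr1/2 DKO HK4. Lost without Smad2/3 DKO HK16 alone, with the adjusted p then reached, were Tgm2 (0.0663), Itga5 (0.0601), Eng (0.0601) and Ly6a (0.0676), and without Tgfbr1/2 DKO HK4 alone Fkbp10 (0.0535) and Gal3st2 (0.0591). Lost in 2 to 4 of the 8 runs, with the highest adjusted p, were Gabre (0.0583), Dkk3 (0.0544), Saa3 (0.0641), Ogn (0.0676), Fbn1 (0.1003), Flna (0.0785), Kcnj8 (0.0629), Mgam (0.0618), Col3a1 (0.0951), Lcn2 (0.0644) and Omd (0.0676). Lost in 5 to 7 of the 8 runs were Serpina3m (0.941), Col6a1 (0.131), Il1r1 (0.131), Wisp2 (0.128), Gpc6 (0.0833), Ccnd1 (0.0881), C3 (0.115), Pgk1 (0.17), Ly6c1 (0.124), Angptl2 (0.138), Cav1 (0.128) and C2 (0.17). The size also moved with single libraries, to 9.79 for Gabra3, 5.89 for Gal3st2, -1.94 for Ly6a and -1.65 for Ly6c1 without control HK3, -2.89 for Fkbp10 without Smad2/3 DKO HK15, -5.99 for Aldh1a2 without control HK6 and 3.62 for Gabre without control HK7. It ran from 4.95 without Smad2/3 DKO HK15 to 6.82 without HK16 for Xist, from -4.75 without HK15 to -3.20 without control HK3 for Kcnj8, from -3.29 without control HK6 to -2.07 without control HK3 for Ccnd1, and from -6.09 without Postn-Cre control HK4 to -3.82 without control HK3 for Lcn2. The values of Serpinb2, Ifi202b, Saa3 and Serpina3m rest on libraries at or near 0 counts and have no exact size. They ran from -17.47 (without Smad2/3 DKO HK16) to -10.80 (without HK15) for Serpinb2, -11.95 (without control HK6) to -7.01 (without Postn-Cre control HK4) for Ifi202b, -11.98 (without Smad2/3 DKO HK16) to -8.20 (without control HK3) for Saa3 and -9.90 (without Smad2/3 DKO HK15) to -1.40 (without Postn-Cre control HK4) for Serpina3m.

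For whole lists the difference passed by camera with the preset correlation for 12, all lower in the Smad2/3 comparison: myeloid markers (adjusted p = 1.28e-08), collagen chains (7.55e-07), collagen processing (1.07e-05), matrix proteases (2.88e-05), endothelial markers (0.000185), contractile genes (0.0011), epicardial markers (0.0011), glycolysis (0.0102), cardiomyocyte markers (0.0232), cytokines (0.0232), cell cycle genes (0.0243) and pericyte markers (0.0243). None of the 12 passed with an estimated correlation (adjusted p 0.567 to 0.614) or with fry (0.0508 to 0.384). With 1 library left out, the first 6 of these lists kept the call in every run. It was lost for epicardial markers without Smad2/3 DKO HK16 (0.0857), for glycolysis without control HK3, Smad2/3 DKO HK16 and Tgfbr1/2 DKO HK4 (up to 0.146), for cardiomyocyte markers without control HK3, control HK6 and Tgfbr1/2 DKO HK2 (up to 0.249) and for cytokines without control HK3, Smad2/3 DKO HK15 and Tgfbr1/2 DKO HK4 (up to 0.225). Cell cycle genes lost it without Postn-Cre control HK4, Smad2/3 DKO HK16, control HK7 and Tgfbr1/2 DKO HK4 (up to 0.0952), and pericyte markers without control HK3, Smad2/3 DKO HK16, control HK7 and Tgfbr1/2 DKO HK4 (up to 0.174).

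The fall of collagen chains in the Smad2/3 DKO libraries had a median of -1.03 on the log2 scale (95% bounds -1.26 to -0.63, from 10000 resamples of the 19 genes), and the list did not pass with an estimated correlation (adjusted p = 0.735). Such bounds, here and in the next paragraph, treat genes as independent and hold none of the variation between libraries, so they are too narrow for genes that move together. An odd state of control HK3, which held more endothelial RNA, is argued against as the whole cause by a median of -0.99 without that library (-1.22 to -0.71), and a trend with transcript length by -0.94 after its removal (-1.21 to -0.58). Female cells without collagen RNA, for which Xist gave a reason to look, would lower the Y-linked genes as far as the collagen chains. Y-linked genes had a median of -0.38, which argues against such cells as the whole cause. The lowest was at -0.57, just above the upper collagen bound of -0.63. Other effects of a different sex make-up were not tested and cannot be told apart from genotype. Loss of Smad2/3 signalling may be the cause, but the 27 other Smad3 target genes had a median of 0.03 (-0.27 to 0.49) with members going both ways, which leaves it open. Differences in RNA quality beyond such a trend and in the activation state of the sorted cells remain open and untested, with the nuclear RNA Malat1 at 27853 and 36029 CPM in the Postn-Cre control libraries and 48941 and 46865 CPM in the Smad2/3 DKO libraries and a median of 0.43 for transcripts of ribosomal proteins.

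The rise of myeloid and epicardial markers in the Tgfbr1/2 DKO libraries had a median of 1.86 for the myeloid list (95% bounds 1.61 to 2.11), and neither list passed with an estimated correlation (adjusted p = 0.774 for both). A lower share of fibroblasts that raises markers of all other cells alike is argued against by the cardiomyocyte markers, with a median of 0.02 (-0.16 to 0.36). This 1 list cannot exclude a lower share of fibroblasts with a gain of only some other cell types, which stays open. Medians were 0.58 for endothelial, 1.41 for erythroid and 0.34 for pericyte markers, against 0.02 for lymphocyte and -0.81 for Schwann cell markers. RNA of macrophages in the sort might account for the myeloid part: a further set of 27 macrophage genes had a median of 1.09 (0.47 to 2.02). Its lower bound falls just short of the 0.5 fixed beforehand, so by that rule it stays open, although the sort took GFP-positive cells. In this set Pf4 (1.72, adjusted p = 0.0219), C5ar1 (2.27, adjusted p = 0.0246) and Sfpi1 (2.95, adjusted p = 0.0463) were called higher. Ncf1 (-0.17) and Ms4a6c (-0.27) lay below 0 and were not called. For Aldh1a2, mesothelial cells stay open. Their keratins and surface genes gained 4.16 CPM together over 8 genes while Aldh1a2 gained 371 CPM. The ratio of these genes to Aldh1a2 in mesothelial cells was not measured, so the gains cannot decide. Among the 8, Krt8, Krt18 and Muc16 were at or near 0 CPM in every library. Lrrn4 was called higher, and Msln (3.14, adjusted p = 0.0991) and Upk3b (2.09, adjusted p = 0.146) lay above 0 without a call. A change of state within the fibroblasts and differences in RNA quality beyond a trend with transcript length, whose removal kept both list calls, could also raise these genes and remain open and untested, with Malat1 at 27421 and 20923 CPM in the Tcf21-Cre control libraries and 8879 and 9317 CPM in the Tgfbr1/2 DKO libraries and a median of 0.47 for transcripts of ribosomal proteins.

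Large changes of single genes such as Gabra3, Cwc22, Ifi202b and Rab6b stood outside the lists. Strain DNA is a candidate explanation, since Cwc22 lies in a segment whose copy number varies between mouse strains. On the chromosomes of the targeted genes lay 2 of the 20 largest called changes in the Smad2/3 comparison (Mmp3 and D0H4S114). In the Tgfbr1/2 comparison 3 of 20 did (Aldh1a2, Rab6b and Zfp949). This argues against strain DNA around the floxed alleles as the whole cause of the 20 changes, through genes on the same chromosomes. The 20 were not limited to genes outside the lists, since Mmp3, Adam12 and Aldh1a2 are list members. The share expected for these chromosomes was not computed, so a part in the cause stays open. Within 10 Mb of the targeted genes lay 1 called gene of 268 tested (Fisher's exact test, p = 0.273) and 13 of 388 (p = 0.692), which decides nothing for the genes there. Called genes with another called gene of unlike name within 1 Mb numbered 39 of 206 (random draws 38 to 70) and 348 of 652 (344 to 400), so local segments elsewhere in the genome stay open. Pairs whose symbols share their first 3 letters were not counted, so these numbers say nothing about Gabra3 and Gabre as a pair. No biological explanation was tested for these genes.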

How the results depend on the processing

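With 2 libraries per group, counts of called genes moved with the test and with single libraries, and the cause was not tested. The alternatives on transcript length, summed entries and sex chromosomes, and those of the list tests of the difference, were chosen after seeing the data. In the Smad2/3 comparison, 206 calls became 819 without the low-count filter and 769 with DESeq2, and ran from 102 (without DKO HK15) to 297 (without control HK4) with 1 library left out. The share of higher calls was 34.5%, against 47.7% without control HK3. In the Tgfbr1/2 comparison, 657 calls became 1229 without the filter, 1134 with DESeq2 and 299 in a fit of all 8 libraries, and ran from 272 (without DKO HK4) to 497 (without control HK6). For the difference, 326 calls became 1195 without the filter and 1150 with DESeq2, and ran from 89 to 302. The correlation of -0.076 between the effects ran from -0.123 to -0.022. DESeq2's type of size factors gave 218, 632 and 358 calls. Without genes on chromosomes X and Y the Smad2/3 comparison had 192.

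In list tests, the 9 lists past the threshold in the Smad2/3 comparison became 0 with an estimated correlation and 0 with fry, and 4 to 11 with 1 library left out (4 without control HK3 and 4 without DKO HK16). The 10 lists in the Tgfbr1/2 comparison became 0 with an estimated correlation and 1 with fry (adipogenic genes), and 9 to 14 with 1 library left out. For the difference, 12 lists became 0 with an estimated correlation and 0 with fry, and 8 to 17 with 1 library left out. None of these list calls was lost on removing the length trend or with DESeq2's type of size factors. Called genes named in the text lost their call on removing the length trend in 3 cases in the Smad2/3 comparison (Mgam 0.0573, Adamts2 0.0749 and Adamts9 0.0828, adjusted p) and in 7 in the Tgfbr1/2 comparison (Angpt1 0.0562, Figf 0.0658, Pparg 0.0525, Cd36 0.0573, Aldoa 0.0599, Hspb1 0.063 and Gpihbp1 0.0615), and with DESeq2's type of size factors in 1 (Cd36 0.0535). Of the called genes named in the text, 27 of 45 in the Smad2/3 comparison, 34 of 79 in the Tgfbr1/2 comparison and 27 of 56 for the difference kept their call without each library in turn. With DESeq2, none of these lost a call. Among uncalled driver and targeted genes the sign turned for Smad3 in the Smad2/3 comparison (0.029 without DKO HK15 and -0.618 without DKO HK16), and in the Tgfbr1/2 comparison for Smad2 with the length trend removed (0.154), Postn without control HK7 (0.202, against -0.834 without control HK6) and Tcf21 without control HK6 (0.202) and DKO HK2 (0.085, against -0.236 without control HK7). Depth limits genes near 0.092 to 0.14 CPM, where 3 counts lie. No paired analysis was possible because the HK numbers name libraries and the groups compared share fewer than 2 of them.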

Other observations

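The 5 lists below were made after seeing which genes were called, so their tests are not independent evidence, and their p-values are unadjusted camera results. Genes of the unfolded protein response, which chaperone secreted proteins, were higher as a list in both DKO groups. In the Tgfbr1/2 comparison 4 of 22 rose (median 0.51, p = 2.93e-05; p = 0.191 with an estimated correlation), and in the Smad2/3 comparison none of 21 was called (median 0.33, p = 0.00795; p = 0.222 with an estimated correlation). The chaperone genes Creld2 and Manf, which were called higher in both, prompted this list and were left out of its tests and counts. Acute-phase and secreted inhibitor genes were higher in the Tgfbr1/2 comparison (4 of 14 rose, median 0.66, p = 0.00214; p = 0.153 with an estimated correlation) and had p = 0.494 in the Smad2/3 comparison, and the difference between the effects had p = 0.00575 (p = 0.0562 with an estimated correlation).

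The list of 42 cytosolic ribosomal proteins passed by camera in the upward direction in both comparisons. The median was 0.43 in the Smad2/3 comparison (40 above 0 and 2 below, 0 called; p = 7.87e-07; p = 0.312 with an estimated correlation) and 0.47 in the Tgfbr1/2 comparison (41 above 0 and 1 below, 1 rose; p = 5.51e-09; p = 0.324 with an estimated correlation). Levels of the nuclear RNA Malat1 were 27853 and 36029 CPM in the Postn-Cre control libraries, 48941 and 46865 CPM in the Smad2/3 DKO libraries, 27421 and 20923 CPM in the Tcf21-Cre control libraries and 8879 and 9317 CPM in the Tgfbr1/2 DKO libraries. Malat1 was itself called in the Tgfbr1/2 comparison. The lists of nuclear long noncoding RNAs and of imprinted genes did not pass in either comparison by camera. Malat1 was not among the 6 nuclear RNAs tested, so that result does not cover it.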
